A study of Arabidopsis thaliana with 4 samples.

How the data were processed

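RNA was measured in whole Arabidopsis thaliana seedlings of the Columbia ecotype after 12 days of growth at 23 °C, in cycles of 16 h of light and 8 h of darkness, on Murashige and Skoog medium with 3% sucrose. The 4 libraries came from wild type, from a mutant of the protein arginine methyltransferase gene PRMT5 (written atprmt5), and from lines m90 and s215. The series design speaks of suppressors of atprmt5 mutants. The labels used here do not say which gene is altered in m90 or s215, nor whether these lines also carry the atprmt5 mutation. Each genotype had 1 library, taken from the genotype label, so no test between genotypes was possible and no p-value is given. Per the labels' protocols, RNA was extracted with Trizol and made into strand-specific libraries by a SMART method.

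Per the submitters' processing notes, reads were handled with TopHat2 2.0.11, an aligner for spliced reads, and the genome build was TAIR10. The values are RPKM (reads scaled by transcript length and library total), deposited by the authors as 1 table of 24288 loci by 4 libraries. The program that counted reads, its use of strand and its treatment of reads with several matches are not given in the sources used here. All 4 value columns matched 1 sample each by name. The table holds 1 value per gene and library, so splicing itself, as retained introns or junction reads, was not analysed here. It names only nuclear loci. Loci of the chloroplast and mitochondrial genomes were not analysed here, although a check of their share had been planned.

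RPKM values were turned back into reads to judge precision. In each library the commonest value times annotated length gave the RPKM of 1 read, and from it the total used for scaling, between 17350612 and 17901205 reads. For all 24288 loci a whole-number length was found at which the values in the 4 libraries were whole numbers of bases of 100-base reads within 1e-05. On 2000 loci with values shifted at random, such a length was found for 38. The smallest such length was used. Among 13572 loci with 1 annotated transcript, it equalled the annotated length for 13.8% and was that length divided by a whole number of at least 2 for 6.56%, where reads are understated and intervals too wide. For most loci it was neither, so the lengths, and with them the reads and intervals, are not checked by the annotation and are approximate. Ratios of RPKM are given with 95% exact intervals (Clopper-Pearson, conditional on the summed reads of the 2 libraries). These intervals cover counting error only: reads without molecular identifiers are not independent molecules, and variation between plants is not in them. Where a library had 0 reads of a gene, the fold is a lower bound against a floor of 3 reads in that library.

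Differences were computed as log2((RPKM + 1)/(RPKM + 1)), which understates the change of genes with low values, among the 18688 loci with a mean of at least 1 RPKM over the 4 libraries. A gene was counted as higher or lower when this ratio reached 2-fold. Some loci passed the minimum only on the libraries where they were high, which favours a difference between those libraries and the others. Libraries were simulated with counting error alone, with a small part of the 18688 loci changed by 2-fold or 4-fold. Among the unchanged loci, between 15 and 36 were counted as higher and between 16 and 24 as lower. In the atprmt5 and wild-type pair the procedure counted 95% of genes simulated at 4-fold and 24% of those simulated at 2-fold. Distances between libraries are the SD of the log2 ratio across genes. Covariances were taken only between pairs of libraries with no library in common, since pairs that share a library vary together by construction. For genes differing between atprmt5 and wild type, the share lying nearer to wild type in m90 or s215 was counted.

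Gene lists were set before the data were examined, as were the comparisons, the thresholds, the rule for naming genes and most alternatives. There were 21 lists with 260 loci, of which 257 are in the table; TSF, NRT2.2 and CRB were not analysed here. A pair of further lists, core histones and cytosolic ribosomal proteins, was found by product name, and the ribosomal list holds only 8 loci because few products are worded that way in the reference. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is not a p-value. A list with fewer than 3 measured members has no median, which left out flowering promoters and floral organ markers. Of 105 medians (21 lists in 5 comparisons), 55 lay in the outer 2.5% on either side, where 5.25 would if genes varied independently. Genes of a list may vary together and the comparisons share libraries, so this excess is not a test.

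Named genes were the 12 highest and 12 lowest by log2 ratio in atprmt5 against wild type, the 10 of each in m90 and in s215 against atprmt5, and the 5 of each in the other pairs, among genes with at least 5 RPKM in 1 of the libraries. PRMT5, FLC, PRR9, FLK, PRP8A and PRP8B were always named, as were up to 4 members of each list with the largest differences among those with at least 1 RPKM in 1 of the libraries. A few further list members are named where a count is spelled out, and were chosen after their values were seen. Names and coordinates come from the TAIR10.1 annotation, which holds 24183 of the loci; 105 loci have no entry there and keep their locus name. Positions are 1-based and are those of the gene. Of 71 genes named by rank or always, 16 overlap a locus on the other strand, among them WRKY40, RRTF1, ORA47, BT5, GSTF12, PYK10, FLC and PRMT5. Their values are uncertain to the extent that reads of both strands were counted.

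Alternatives were a pseudocount of 0.1, no filter on low values, a mean of at least 5 RPKM, centring on the median of genes with at least 5 RPKM in all 4 libraries, rescaling to equal total RPKM and a 1.5-fold threshold. Added after the data had been seen were centring within 10 by 10 bins of GC content and exonic length, and a filter computed without the s215 library. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with matplotlib 3.10.9 for figures. The procedures were tested on simulated data before use.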

Results

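RNA levels were compared between 12-day-old seedlings of wild type, the atprmt5 mutant and the lines m90 and s215, in the setting of a study on suppressors of atprmt5 and on the role of AtPRMT5 in splicing. AtPRMT5 is an enzyme that dimethylates arginines, with Sm proteins of the spliceosome among its known substrates. Each genotype was measured once, so there are no replicates, and every difference below is between 2 libraries rather than between genotypes. Scaling totals were 17350612 reads in wild type, 17901205 in atprmt5, 17802377 in m90 and 17378981 in s215. The s215 library had 2893 loci at 0, against 1882 in wild type, 1736 in atprmt5 and 1884 in m90. Brackets after a ratio hold its 95% counting interval.

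The transcript of PRMT5 itself (AT4G31120, chromosome 4, 15132011 to 15136696, minus strand, 23 exons) stood at 5.94 RPKM in wild type and 1.25 RPKM in atprmt5, a ratio of 0.210 (0.153 to 0.287). It was low in both other lines as well. The level was 0.974 RPKM in m90, 0.164 of wild type (0.113 to 0.229), and 1.70 RPKM in s215, 0.287 of wild type (0.215 to 0.377). The levels in m90 and s215 were not separable from that in atprmt5 at this depth, with ratios of 0.781 (0.493 to 1.19) and 1.37 (0.926 to 1.99). Of 9 measured arginine methyltransferases, PRMT5 was the 1 member at least 2-fold lower in atprmt5 and in m90 than in wild type, and 0 were higher. The list median lay at percentile 60.9 in atprmt5. In s215, PRMT1A was also low, at 1.23 RPKM against 5.92 in wild type and 6.98 in atprmt5.

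Wild type, atprmt5 and m90 resembled one another, and s215 stood apart. The SD of the log2 ratio across 18688 genes was 0.50 between atprmt5 and wild type, 0.50 between m90 and wild type and 0.58 between m90 and atprmt5. It was 1.35 between s215 and atprmt5, 1.39 between s215 and wild type and 1.43 between s215 and m90. Counting error alone gave 0.17 in simulated libraries. In s215, 5 of 7 root markers were at least 2-fold lower than in wild type, PYK10 and CASP1 among them, and 2 were higher, FRO2 and NRT2.1.

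**Figure D1:**
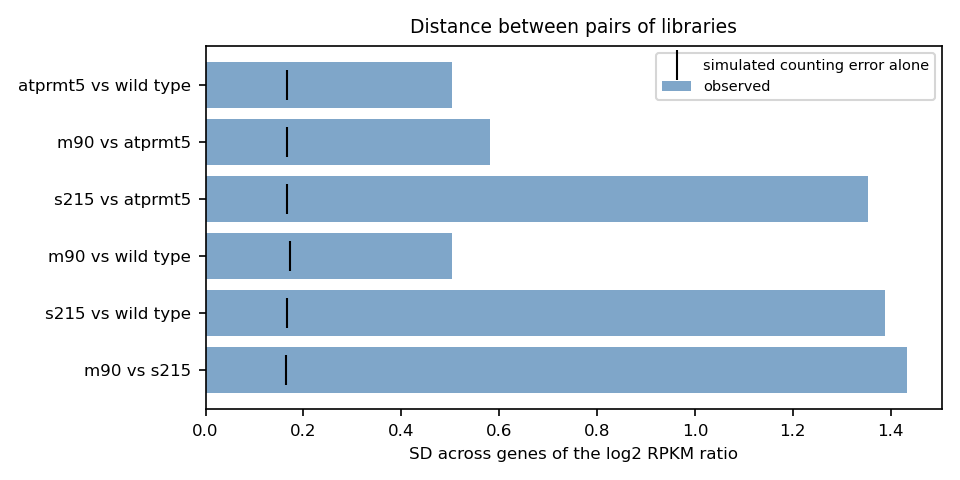
Bars give the SD across 18688 genes of the log2 RPKM ratio (horizontal axis, log2 units) for each of the 6 pairs of libraries, and black lines give the SD from simulated counting error alone. The 3 pairs with s215 lie at 1.35 to 1.43, and the other 3 at 0.50 to 0.58.

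The first comparison asked what differs in atprmt5 seedlings. Transcripts of anthocyanin synthesis were higher in the atprmt5 library than in wild type. The genes with the lowest ratios included the regulators WRKY40, RRTF1 and ORA47, a grouping read from the ranking and not from a list fixed in advance. DFR, which makes leucoanthocyanidins (AT5G42800, chromosome 5, 17164093 to 17166032), was at 82.3 against 2.54 RPKM, 32.5-fold higher (25 to 42.5). WRKY40, a transcription factor of stress responses (AT1G80840, chromosome 1, 30383561 to 30385499), was at 7.58 against 172 RPKM, a ratio of 0.0442 (0.0375 to 0.0517). The iron deficiency list had a higher median, with 6 of 18 genes past 2-fold, and the heat shock list a lower one, with 3 of 9. In all, 336 genes were at least 2-fold higher and 620 at least 2-fold lower.

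Of 13 measured flavonoid and anthocyanin genes, 9 were at least 2-fold higher in atprmt5 and 0 lower, and the median log2 ratio of 1.95 lay above all 10000 random lists. LDOX was 13.8-fold higher (11.4 to 16.9), the glycosyltransferase gene UF3GT 24.6-fold (14.2 to 46.7), and GSTF12, a glutathione transferase needed for anthocyanin transport, 10.7-fold (8.90 to 13.0). The malonyltransferase gene 5MAT stood at 9.0 against 0.640 RPKM. The chalcone synthase gene CHS, which opens the pathway, was 3.92-fold higher (3.69 to 4.16), and PAP1, a MYB activator of the pathway, was at 7.02 against 1.39 RPKM. The acyltransferase locus AT1G03940 (9.37 against 0.584 RPKM) was also among the 12 highest genes. The other 6 were the nudix hydrolase gene NUDT24 (53.1 against 3.96 RPKM), the cytochrome P450 locus AT3G44970 (26.5 against 2.59 RPKM), the pathogenesis-related gene PR1 (13.1 against 1.21 RPKM), AT1G77960, AT2G16586 and AT2G01010. The last of these is a ribosomal RNA locus with near-identical copies in the genome, and its 8.83-fold difference is uncertain for that reason.

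**Figure D2:**
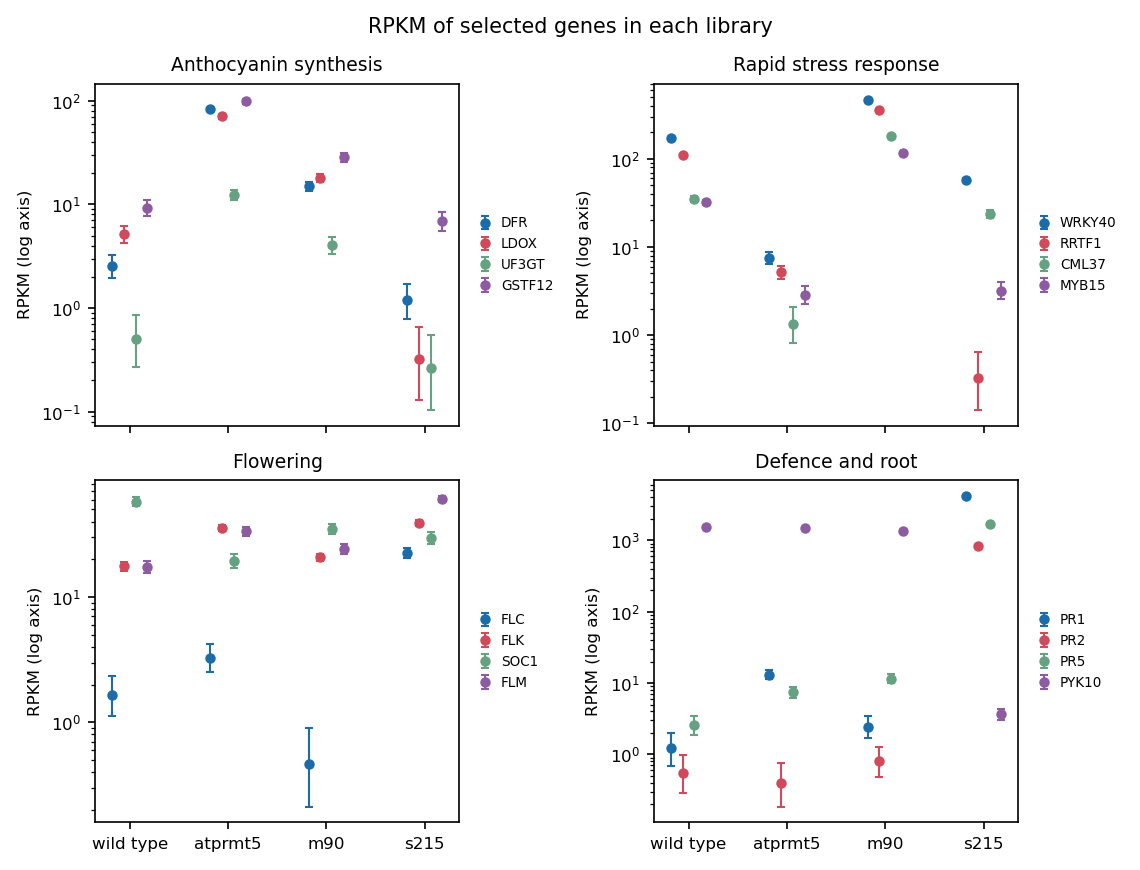
Points give the RPKM (log axis) of 16 genes in the 4 libraries, and error bars are 95% exact Poisson intervals of the reads, which cover counting error only; values of 0 cannot be drawn. DFR stands at 2.54 RPKM in wild type, 82.3 in atprmt5, 14.9 in m90 and 1.18 in s215, and WRKY40 at 172, 7.58, 469 and 57.3.

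Among the 12 lowest genes were the ERF factor RRTF1 (5.16 against 110 RPKM, ratio 0.0471, 0.0391 to 0.0562), the calmodulin-like gene CML37 (1.34 against 35.0 RPKM, ratio 0.0383, 0.0228 to 0.0605) and ORA47, a regulator of jasmonate synthesis (3.16 against 40.6 RPKM). BT1, BT2 and BT5, which encode BTB and TAZ domain proteins, were at 13.2, 19.1 and 3.50 RPKM in atprmt5 and at 154, 182.1 and 41.4 RPKM in wild type. PROPEP3, the precursor of a defence elicitor peptide, had 0 reads in atprmt5 and 8.89 RPKM in wild type, at least 12.9-fold lower. The ARM repeat locus AT3G02840, the glycine-rich loci AT2G05510 and AT2G05540 and the VQ motif locus AT2G22880 completed the 12. WRKY33 and WRKY53, in the defence list, were at 0.154 (0.144 to 0.165) and 0.135 (0.102 to 0.177) of wild type. The salicylic acid and pathogen defence list as a whole had 2 of 15 members higher and 3 lower, with a median of -0.06 at percentile 32.5.

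In the abscisic acid, salt and cold list, 5 of 18 members were lower and 0 higher, with a median of -0.43 at percentile 0.04. They were DREB2A (6.02 against 37.4 RPKM), NCED3, a rate-limiting gene of abscisic acid synthesis (3.12 against 14.8), CBF1, CBF2 and RAB18. In the heat shock list 3 of 9 were lower and 0 higher, with a median of -0.72 below all random lists. HSP90.1 was at 34.9 against 74.3 RPKM. In the jasmonate list 2 of 9 were higher, AOC1 and LOX2, and 2 lower, JAZ1 and VSP1, with a median at percentile 52.3.

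Of 18 iron deficiency genes, 6 were higher and 0 lower, with a median of 0.43 at percentile 99.99. The iron transporter gene IRT1 was 8.51-fold higher (6.05 to 12.3), the nicotianamine synthase gene NAS2 6.92-fold (5.08 to 9.59), and the regulator BHLH39 3.08-fold (2.38 to 4.02); FRO2, BHLH38 and NAS4 were the others. The ferritin genes had no member past 2-fold and a median at percentile 38.0. Of 7 measured root markers 4 were higher, at a median of 1.02 above all random lists, whereas 12 further root-enriched genes, listed after the data had been seen, had 0 higher, 2 lower and a median of -0.30 at percentile 1.69. Of the 4 higher markers IRT1 and FRO2 are also on the iron list, and the others were NRT2.1 and EXPA7. PYK10, the most abundant root marker, was at 1484 against 1553 RPKM. In the seed storage list, 2 of 3 measured members were lower: the cruciferin genes CRA1 (19.2 against 67.8 RPKM) and CRC (14.4 against 89.3 RPKM), at a list median of -1.76.

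FLC, a repressor of flowering (AT5G10140, chromosome 5, 3173382 to 3179448, minus strand), was at 3.28 RPKM in atprmt5 and 1.66 RPKM in wild type, 1.97-fold higher (1.24 to 3.09). FLK, an autonomous pathway gene that acts to lower FLC (AT3G04610, chromosome 3, 1250553 to 1254984), was at 35.6 against 17.55 RPKM, 2.03-fold higher (1.84 to 2.24). FLM was at 33.4 against 17.41 RPKM. The promoter of flowering SOC1 was at 19.5 against 57.8 RPKM, a ratio of 0.337 (0.289 to 0.392). FT was at 1.15 RPKM in wild type and lower elsewhere, at 0.0653 in atprmt5, 0.131 in m90 and 0 in s215. No fold is given for FT at these low levels. Neither the 7 measured flowering repressors nor the 7 autonomous pathway genes had a member counted as 2-fold different on the log2(RPKM + 1) scale, and their medians lay at percentiles 82.0 and 83.0. Only 2 members of the flowering promoters (SOC1 and FUL) and 2 of the floral organ markers (PI and SEP3) were measured, and of these SOC1 alone passed 2-fold in this pair.

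In the clock, LHY was 4.53-fold higher in atprmt5 (4.02 to 5.10) and RVE8 2.85-fold (2.23 to 3.65), while RVE1 was at 14.5 against 37.1 RPKM. PRR9 (AT2G46790, chromosome 2, 19232607 to 19235179) was 1.44-fold higher (1.30 to 1.61). The morning-phased list had a median of -0.10 at percentile 27.0. All 11 evening-phased genes had a log2 ratio below 0, though none reached 2-fold, and their median of -0.40 lay at percentile 0.46. PRR5 was at 7.38 against 13.0 RPKM.

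Transcripts of the splicing machinery differed little between these 2 libraries. For the Prp19 complex (NTC), the spliceosome assembly in the title of the series, 0 of 18 members passed 2-fold, and the median of -0.02 lay at percentile 46.5. MAC3A was at 18.5 against 19.8 RPKM and CDC5 at 165 against 186. The core snRNP list had 0 of 20 past 2-fold, with a median of 0.16 at percentile 96.5. PRP8A, encoding the central protein of the spliceosome (AT1G80070, chromosome 1, 30117847 to 30127811, 24 exons), was at 34.2 against 31.2 RPKM, 1.10-fold higher (1.05 to 1.14). Its paralog PRP8B was at 0.717 against 0.226 RPKM, under the expression minimum. Of 20 SR splicing factor genes 1 was higher, RSZ22A (29.6 against 13.6 RPKM), and the list median lay at percentile 75.6.

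Genes grouped by exon number gave small shifts in this pair. For 2361 genes with 1 exon the median log2 ratio was -0.10, with 2.75% at least 2-fold higher and 9.23% lower. For 7655 genes with 2 to 5 exons it was -0.03, and for 8208 genes with 6 or more exons 0.04, with 1.40% higher and 0.792% lower. The first 2 medians lay below all random lists and the third above. With so many genes per class random medians vary little, so these positions say little about the size of the shifts. The exon classes were not recomputed after centring on GC content and exonic length.

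Cell cycle genes had a median of 0.45, above all random lists, although only CYCB1-1 of 18 passed 2-fold (6.38 against 2.19 RPKM). Core histones had a median of 0.32, also above all random lists, with 3 of 37 higher and 1 lower. Histone genes are near-identical in sequence, so values of single members are uncertain. None of 23 nuclear photosynthesis genes passed 2-fold, with a median at percentile 83.0, nor did any of 7 ribosomal protein genes, at percentile 54.1.

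The second comparison asked how m90 differs from atprmt5. The regulators WRKY40, CML37 and RRTF1 had some of the highest ratios, again read from the ranking, and heat shock transcripts were higher as a list. Anthocyanin and iron deficiency transcripts were lower. WRKY40 reached 469 RPKM in m90, 61.8-fold above atprmt5 (53.0 to 72.7), CML37 180 RPKM, 134-fold (85.9 to 224), and RRTF1 359 RPKM, 69.6-fold (58.4 to 83.5). DFR was at 14.9 RPKM, 0.182 of atprmt5 (0.162 to 0.203). Seed storage transcripts were close to missing in m90. In all, 679 genes were at least 2-fold higher in m90 and 438 lower.

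The other genes among the 10 highest were AT3G02840 (115.2 RPKM in m90), ERF13 (69.0), MYB15 (115.4), BPS3 (69.2), the nuclease locus AT4G29780 (695), AT5G45630 (106) and DDF1 (88.9). In atprmt5 the last 6 of these were between 1.26 (ERF13) and 29.3 RPKM (AT4G29780). In the heat shock list 6 of 9 were higher and 0 lower, at a median of 1.51 above all random lists. The heat shock factor gene HSFA2 was at 26.5 against 0.629 RPKM, 42.1-fold (21.1 to 98.3), and HSP101 at 20.8 against 3.38. Of 18 abscisic acid, salt and cold genes 6 were higher and 1 lower, with a median of 0.47 above all random lists; DREB2A was 19.3-fold higher (16.5 to 22.8) and RD29B lower, at 5.79 against 29.0 RPKM. In the defence list 4 of 15 were higher and 1, PR1, lower, with a median of 0.37 at percentile 99.66. The jasmonate median of 0.58 lay at percentile 99.89, with 2 of 9 higher, among them JAZ1 (147 against 16.1 RPKM).

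Of 13 flavonoid genes 8 were lower in m90 than in atprmt5 and 0 higher, at a median of -1.09 below all random lists. LDOX was at 0.254 of atprmt5 (0.227 to 0.283) and CHS at 0.466 (0.444 to 0.489). Of 18 iron deficiency genes 8 were lower and 1, PYE, higher, at a median of -0.64 below all random lists. BHLH38 was at 3.2 against 32.9 RPKM and NAS2 at 3.15 against 19.4. The 3 ferritin genes had a median of 0.72 at percentile 99.34. Root markers had 2 of 7 lower and a median of -0.86 at percentile 0.01, but the 12 further root-enriched genes showed no such shift (1 higher, 0 lower, median -0.05, percentile 49.4), and PYK10 was at 1367 RPKM against 1484. All 3 measured seed storage genes were lower: CRA1 was at 0.157 against 19.2 RPKM, CRC had 0 reads, at least 154-fold lower, and OLEO1 had 0 against 4.06 RPKM. The list median was -3.95. These 3 genes passed the expression minimum on their levels in wild type and atprmt5, which favours lower values in m90. The seed aquaporin gene TIP3;1 and the late embryogenesis loci AT4G21020 and AT3G53040 were also among the 10 lowest. The rest were NUDT24 (6.35 against 53.1 RPKM), DIN2 (2.87 against 31.6), AT4G28790 (1.21 against 17.79), BHLH38 and the ribosomal RNA locus AT2G01010.

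FLC was at 0.467 RPKM in m90, 0.142 of its level in atprmt5 (0.0638 to 0.295) and 0.281 of wild type (0.118 to 0.609), and was the 1 of 7 flowering repressors counted as lower than in atprmt5. FLK stood at 20.7 RPKM, 0.582 of atprmt5 (0.531 to 0.636) and 1.18-fold above wild type (1.06 to 1.31). SOC1 was at 35.0 RPKM, 1.80-fold above atprmt5 (1.53 to 2.12). PRR9 was at 15.4 RPKM, 0.593 of atprmt5 (0.530 to 0.663). LHY was at 24.9 RPKM in m90 and 6.07 in wild type. Of the clock lists, 1 morning gene (RVE1) and 1 evening gene (BOA) were 2-fold higher than in atprmt5, with medians at percentiles 82.3 and 35.1. The NTC, core snRNP and SR lists had 0 members past 2-fold against atprmt5, with medians at percentiles 46.7, 79.6 and 28.4. PRP8A was at 30.02 RPKM, 0.878 of atprmt5 (0.841 to 0.917).

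Medians of the exon classes against atprmt5 were -0.02 for 1 exon, with 11.1% higher and 5.38% lower, 0.01 for 2 to 5 exons and -0.07 for 6 or more. Cell cycle genes had a median of 0.19 at percentile 98.04 and core histones 0.18 at percentile 99.72, with 0 members past 2-fold in either list. Neither held in every alternative: cell cycle lay at percentile 93.3 at a mean of at least 5 RPKM, and core histones had a median of -0.03 with the trend in GC content and length removed. For photosynthesis and ribosomal protein genes 0 members passed 2-fold, with medians at percentiles 12.9 and 96.0, and the autonomous pathway median was at percentile 54.5. No arginine methyltransferase passed 2-fold (percentile 63.4), and the flowering repressor median lay at 56.5.

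Against wild type, 487 genes were at least 2-fold higher in m90 and 489 lower. HSFA2 was 22.5-fold higher (13.0 to 39.3), the zinc finger gene ZAT7 10.7-fold (8.29 to 13.95), AT1G14200 8.04-fold (6.75 to 9.66) and WRKY46 6.28-fold (5.76 to 6.85), with AT3G48650 at 7.44 against 0.504 RPKM. CRC was at least 953-fold lower, CRA1 was at 0.00231 of wild type (0.000751 to 0.00541), and TIP3;1, BGLU19 and the late embryogenesis locus AT3G17520 were the other lowest genes. Anthocyanin genes remained above wild type, with 7 of 13 higher, 0 lower and a median of 1.10 above all random lists. Defence genes had 5 of 15 higher and a median of 0.50, cell cycle genes 4 of 18 higher and 0.67, and core histones 9 of 37 higher and 0.52, all at percentile 99.95 or above. Heat shock (0.31, percentile 98.3), jasmonate (0.58, 99.89) and ferritin (0.62, 98.6) medians were also above most random lists, although heat shock fell to percentile 96.9 with the trend in GC content and length removed. The evening clock median was -0.58, below all random lists, with PRR5 at 4.93 against 13.0 RPKM. In the core snRNP list, SMD1A (7.2 against 2.98 RPKM) and LSM5 (23.3 against 11.01) were higher, at a median of 0.25 and percentile 99.54. That percentile was 97.36 once the trend with GC content and length was removed. Seed storage genes had a median of -5.89, below all random lists, with all 3 lower. These 3 passed the expression minimum on their levels in wild type and atprmt5, which favours such a position. Lists within the bulk of random lists were NTC (percentile 61.0), SR (82.0), arginine methyltransferases (96.0), flowering repressors (42.7), autonomous pathway (86.3), photosynthesis (34.8) and ribosomal proteins (79.7), with PRMT5 as the only member past 2-fold. Of 18 iron deficiency genes 2 were higher (IRT1 and FRO2) and 2 lower (BHLH38 and BHLH101), at percentile 96.1, and the root marker median lay at 40.5. Of 18 abscisic acid, salt and cold genes 3 were higher and 1 lower (91.05), and of 8 morning clock genes 2 were higher, LHY and RVE8 (75.1). Medians by exon number were -0.07, -0.02 and -0.04.

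The third comparison set s215 against atprmt5. Salicylic acid defence transcripts were far higher in the s215 library, and transcripts of roots, dividing cells, iron uptake and photosynthesis were far lower. PR1, a marker of salicylic acid signalling (AT2G14610, chromosome 2, 6241640 to 6242541), was at 4144 RPKM against 13.1 in atprmt5, 317-fold (273 to 369), and 1.21 in wild type. PYK10, a root and seedling beta-glucosidase of ER bodies (AT3G09260, chromosome 3, 2840477 to 2843781), was at 3.65 RPKM against 1484 in atprmt5, a ratio of 0.00246 (0.00204 to 0.00296). In all, 2370 genes were at least 2-fold higher in s215 and 4332 lower. The median log2 ratio of all tested genes was -0.12 against atprmt5 and -0.15 against wild type, and rescaling to equal totals brought both to 0.01; list medians below are to be read against that shift.

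All 15 measured defence genes were at least 2-fold higher in s215 than in atprmt5, at a median of 3.62 above all random lists. Some, such as PR2 and FRK1 (11.8 RPKM in s215 against 0.373), passed the expression minimum only on their s215 level. These could only come out higher, and the list was not recomputed without them. PR2 was at 830 against 0.403 RPKM, 2063-fold (1086 to 4512), and PR5 at 1699 against 7.47, 228-fold (192 to 272). The other genes among the 10 highest were PCR1 (309 RPKM in s215), AIG1 (611), AT3G28510 (613), LURP1 (852), AT5G10760 (303), HR4 (1493) and AT2G04460, which had 0 reads in atprmt5 and was at least 1645-fold higher. Regulators of the pathway were higher by less: ICS1 was at 41.9 against 7.14 RPKM and WRKY70 at 420 against 32.5. The ferritin genes FER1 and FER4 were higher and FER3 lower. The ferritin median was 1.71, at percentile 98.98.

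Of 7 root markers 5 were lower and 0 higher, at a median of -3.10 below all random lists. CASP1, of the root endodermis, had 0 reads in s215, at least 48.1-fold lower than in atprmt5. Beside PYK10, the jacalin-related lectin genes JAL33 and JAL22 and the ER body gene NAI2 were at 0.674, 0.606 and 1.5 RPKM in s215 and at 473, 229 and 328 RPKM in atprmt5. MLP34, AT2G33850, AT4G11320, AT4G33550, AT1G13650 and the iron peptide gene IMA2 completed the 10 lowest; IMA2 had 0 reads, at least 274-fold lower. Of 18 iron deficiency genes 14 were lower and 1 higher, at a median of -3.49. Of 13 flavonoid genes 11 were lower, with CHS at 5.06 against 198 RPKM, and 1 was higher, PAP2, at 5.51 RPKM against 0. The flavonoid median was -3.25, below all random lists.

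Of 18 cell cycle genes 14 were lower, at a median of -2.44 below all random lists, and 1 was higher. CYCB1-2 was at 0.274 against 16.2 RPKM. Core histones had 17 of 37 lower and 2 higher, at a median of -0.93. Of 23 photosynthesis genes 21 were lower and 0 higher, at a median of -1.75 below all random lists, with LHCA1 at 638 against 4365 RPKM and RBCS3B at 110 against 1143. CAB1 and CAB2 are near-identical neighbours that share reads, and their separate values, 10357 and 1691 RPKM in s215, are uncertain. Both measured floral organ markers and all 3 seed storage genes were lower. The seed storage median was -3.82, at percentile 0.05, for genes that passed the expression minimum on wild type and atprmt5. FUL, a promoter of flowering, was higher, at 12.0 against 1.07 RPKM.

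FLC was at 22.6 RPKM in s215, 6.88-fold above atprmt5 (5.31 to 9.22) and 13.6-fold above wild type (9.34 to 20.07). Of 7 flowering repressors 4 were higher than in atprmt5, at a median of 1.15 and percentile 99.56, with MAF5 at 25.6 against 5.15 RPKM. FLK was at 38.8 RPKM, 1.09-fold above atprmt5 (1.01 to 1.18). PRR9 was at 59.2 RPKM, 2.28-fold (2.1 to 2.47), and LHY at 148, 5.38-fold (5.10 to 5.68). In the clock lists 3 of 8 morning and 5 of 11 evening genes were higher and 0 and 1 lower, with medians of 0.82 and 0.87 at percentiles 98.3 and 99.76.

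For the splicing lists, 2 of 18 NTC genes were higher in s215 than in atprmt5: CDC5 (352 against 165 RPKM) and SKIP (225 against 82.5). The list median of 0.25 lay at percentile 88.6. Of 20 SR genes 1 was higher, RS40 (275 against 73.1 RPKM), at a median of 0.39 and percentile 96.2. Of 20 core snRNP genes 1 was higher, BRR2B, and 2 lower, U1A and SMD1B, at percentile 72.7. PRP8A was at 53.2 RPKM, 1.56-fold above atprmt5 (1.5 to 1.62). Medians by exon number were -0.38, -0.22 and -0.00 for 1, 2 to 5 and 6 or more exons. The abscisic acid, salt and cold list had 4 of 18 higher and 4 lower (percentile 91.3), heat shock 0 of 9 higher and 3 lower (3.35), jasmonate 2 of 9 each way (83.5) and autonomous pathway 2 of 7 higher (52.2). The ribosomal protein list, which holds only the few loci found by product name, had 0 of 7 past 2-fold. Its median lay at percentile 52.4, and that of arginine methyltransferases, with PRMT1A lower, at 43.6.

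Against wild type, s215 had 2368 genes higher and 4546 lower. PR1 was 3415-fold higher (2103 to 5976), PR2 1500-fold (858 to 2903), PR5 657-fold (489 to 904), LURP1 1517-fold (770 to 3515) and AT3G28510 1781-fold (995 to 3569). PYK10, JAL33, MLP34, AT4G11320 and AT2G37870 were the lowest, PYK10 at 0.00235 of wild type (0.00195 to 0.00283). Of 15 defence genes 13 were higher and 1 lower, WRKY40, at 57.3 RPKM in s215 against 172 in wild type. Members such as PR2 and FRK1 again passed the expression minimum only on s215. List medians were 3.17 for defence, -1.76 for cell cycle, -1.95 for iron deficiency, -1.69 for photosynthesis, -1.56 for root markers (5 of 7 lower and 2 higher) and -1.46 for heat shock, all in the outer 2.5% of random lists. For root markers this was lost, at percentile 3.55, once the trend with GC content and length was removed. The SR list had a median of 0.57 at percentile 99.4 and the core snRNP list 0.50 at percentile 98.7. Removing the trend with GC content and length brought these to percentiles 97.45 and 93.2. The NTC median of 0.35 lay at percentile 94.5. Flowering repressors had 5 of 7 higher, at a median of 1.49 and percentile 99.89, and morning clock genes 4 of 8 higher, at 1.0 and percentile 99.5. Ferritins had 2 of 3 higher and 1 lower, at 1.23 and percentile 97.54, a position lost in 3 alternatives (97.4, 96.8 and 97.1). Core histones had 2 of 37 higher and 18 lower, at -0.83, which moved to percentile 13.7 with the trend in GC content and length removed. Seed storage genes had all 3 lower, at -5.85, after the same selection on wild type and atprmt5. The other medians were at percentiles 94.8 (evening clock, 2 of 11 higher and 2 lower), 88.5 (autonomous pathway, 2 of 7 higher), 34.3 (abscisic acid, salt and cold, 2 of 18 higher and 7 lower), 43.3 (jasmonate, 3 of 9 higher and 2 lower), 8.87 (flavonoid, 2 of 13 higher and 5 lower), 61.05 (ribosomal proteins, 1 of 7 lower) and 47.7 (arginine methyltransferases, PRMT5 and PRMT1A lower). Medians by exon number were -0.51, -0.28 and 0.02.

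**Figure D3:**
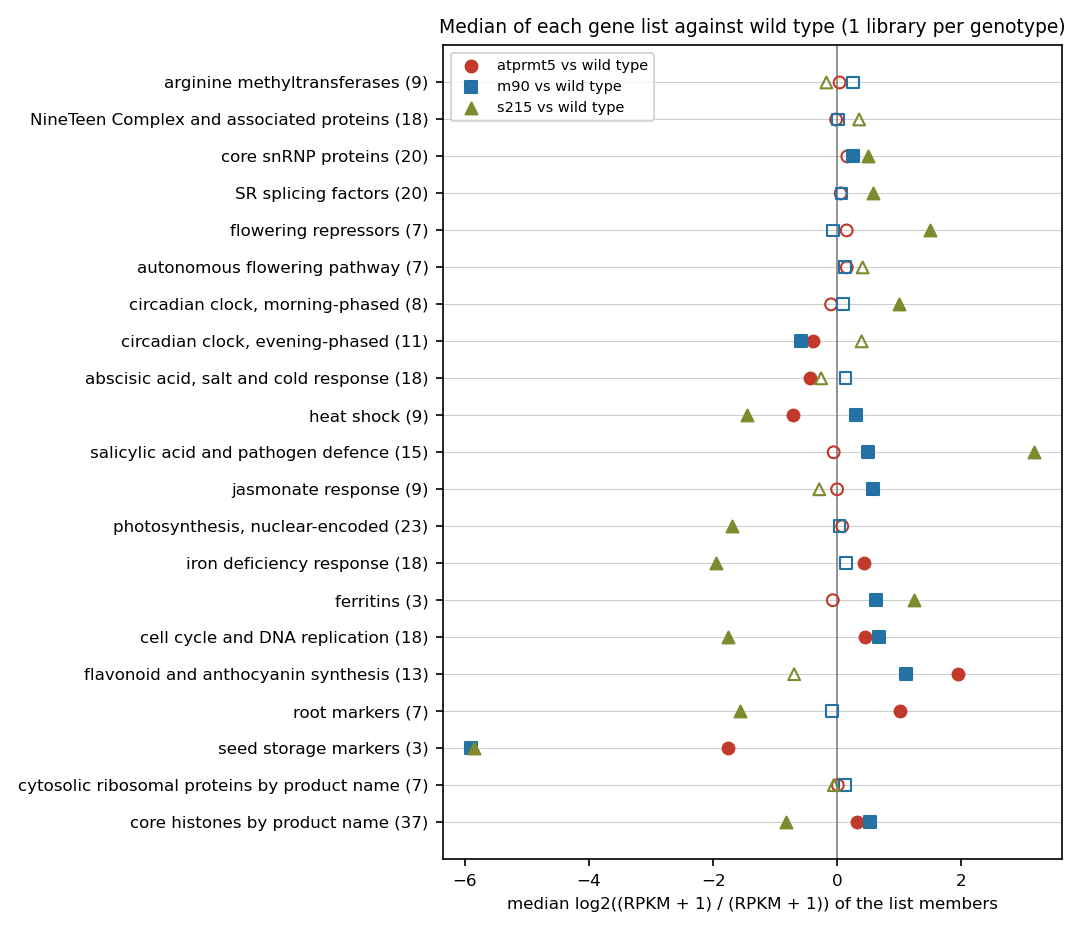
Each symbol gives the median log2((RPKM + 1)/(RPKM + 1)) (horizontal axis) of a gene list against wild type, for atprmt5 (circles), m90 (squares) and s215 (triangles), with the number of measured members in brackets. Filled symbols lie in the outer 2.5% of 10000 random lists matched on expression, such as defence in s215 at 3.17 and flavonoid genes in atprmt5 at 1.95, and open symbols do not.

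Between the lines, 4701 genes were at least 2-fold higher in m90 than in s215 and 2840 lower. The extremes repeated the genes above. RRTF1 was at 359 RPKM in m90 and 0.329 in s215, and PYK10, JAL33, AT2G33850 and MLP34 followed, while PR1, PR2, PCR1, AT3G28510 and LURP1 were highest in s215. PCR1 had 0 reads in m90 and was at least 1404-fold higher in s215.

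A last question was whether m90 and s215 lay nearer to wild type where atprmt5 differed. Of the 336 genes higher in atprmt5, 60.1% were nearer to wild type in m90 and 57.1% in s215. Of the 620 lower in atprmt5, 62.4% were nearer to wild type in m90, and 29.0% in s215. For comparison, of the 487 genes higher in m90 than in wild type, atprmt5 was nearer to wild type for 69.0%, and of the 489 lower, for 48.3%. For s215 these shares were 69.0% and 37.8%. Its low share among lower genes thus also appeared in a set chosen on m90. Genes that also differed in atprmt5 were not removed from that set, and both sets share the wild-type library. Whether the low share is limited to genes differing in atprmt5 was therefore not tested. Differences without a common library had covariances of -0.0892 (atprmt5 minus wild type with m90 minus s215), 0.0201 (m90 minus wild type with atprmt5 minus s215) and 0.109 (s215 minus wild type with atprmt5 minus m90). With a pseudocount of 0.1 the second was 0.000549 and the first -0.142. At that setting the shares for genes higher in atprmt5 were 54.0% in m90 and 50.2% in s215. At a mean of at least 5 RPKM the s215 share for these genes was 50.5%.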

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

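The tests on photosynthesis transcripts, on PRMT5 in s215, on clock genes, on albumins and on the unselected dry-seed genes were chosen after their results had been seen, and so were the centring on GC content and the extra gene lists; the bounds of the other tests were written before their values were known, and of these the root-enriched, senescence, touch and wound and dry-seed tests used lists drawn up once the patterns had been seen, while the GC content test used the planned defence list. Since each genotype has 1 library, genotype itself stays open and untested for every pattern below.

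The cell cycle list stood out because its medians against atprmt5 lay on opposite sides, 0.19 in m90 and -2.44 in s215, each outside the bulk of random lists. For m90 this was lost at a mean of at least 5 RPKM, where the median lay at percentile 93.3. The difference between the lines was not tested.

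The s215 library stood apart from the other 3. Removing the trend with GC content and length left the defence median against wild type at 3.06, so this trend does not account for the defence shift. Distances between libraries were not recomputed after that correction. It took core histones (percentile 13.7), root markers (3.55), core snRNP (93.2) and SR (97.45) out of the outer 2.5%, so it may account for part of the pattern. Missing roots would not lower shoot transcripts, yet the photosynthesis median was -1.69. Missing or few roots could account for low root transcripts, since 91.7% of 12 further root-enriched genes, listed after the pattern was seen, were at least 8-fold lower than in wild type, but of the 7 planned root markers FRO2 and NRT2.1 were higher and their list left the outer 2.5% of random lists (percentile 3.55) with GC content and length removed. Older leaves could account for high senescence transcripts, at least 2-fold higher for 70.0% of 10 genes also listed afterwards, with SAG29 and SEN1 lower, and no test links them to the defence, cell cycle, iron or photosynthesis lists. A wild-type sample under this label stays undecided. PRMT5 was at 0.287 of wild type (0.215 to 0.377), under the bound at which this explanation was to fail. That bound was set aside because PRMT5 may be low in any tissue with few dividing cells, which was not tested. Harvest time was not tested for s215. Its clock medians against wild type were 1.0 for morning genes (percentile 99.5) and 0.39 for evening genes (percentile 94.8). Which of these differences came with the s215 genotype, the tissue collected or the time of harvest stays open.

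Rapidly induced genes were low in atprmt5 and high in m90. Between m90 and atprmt5, the median size of the log2 ratio was 0.18 over 19 clock genes and 3.09 over 12 touch and wound response genes. This argues against harvest times far apart, although the clock genes RVE1 and BOA passed 2-fold. A short offset in harvest time cannot be excluded by clock genes and stays open. For atprmt5 and wild type, different harvest times cannot be told apart from genotype, because evening clock genes had a median of -0.40 and all 11 lay below 0. The 12 touch and wound response genes, among them ZAT10, ERF6 and CML38, had medians of -1.57 in atprmt5 against wild type and 3.09 in m90 against atprmt5. These genes were listed after WRKY40, RRTF1 and CML37 had been seen to behave this way, so their medians extend the description and give no weight to handling at harvest over genotype, and both stay open.

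The cruciferin transcripts CRA1 and CRC were highest in wild type, lower in atprmt5 and close to missing in m90. The albumin gene SESA1, at low levels, ran against this order (0.41 RPKM in wild type, 1.51 in atprmt5 and 0.16 in m90). Seed storage genes were about as low in s215 as in m90, with list medians against wild type of -5.85 and -5.89. The measured genes passed the expression minimum on their wild-type and atprmt5 levels, which favours low medians in m90 and s215. Leftover seeds in the sample would bring all abundant seed transcripts, but the 4 albumin genes averaged 0.394 RPKM in wild type against 78.5 for the cruciferins CRA1 and CRC, a ratio of 0.00502. The albumin genes resemble one another, and reads shared between them might have been dropped before counting, which weakens this argument. The median of 6 further dry-seed genes was -1.52 in m90 against wild type and -0.91 in atprmt5, but they were selected for at least 1 RPKM in wild type, which favours lower values elsewhere. With no selection, 9 of 10 such genes were lower than in wild type both in m90 (median -1.09) and in atprmt5 (median -0.56). In s215 all 10 were lower, also at a median of -1.09. Many were at very low levels, and genotype, seed age and the pace of growth are all untested.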

How the results depend on the processing

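The GC content and length correction and the filter without s215 were chosen after the data had been seen; the other alternatives were planned. No paired analysis was possible because each genotype has 1 library. Of the differences counted as such, 1 reversed its sign: core histones in m90 against atprmt5, from 0.18 to -0.0316 (percentile 51.2) with GC content and length removed. The median over all tested genes changed sign at equal totals in the pairs with s215. It went from -0.12 to 0.01 in s215 against atprmt5, from -0.15 to 0.01 against wild type and from 0.10 to -0.09 in m90 against s215. In atprmt5 against wild type it went from -0.003 to 0.018. Centring turned the medians of the pairs without s215 from slightly negative to slightly positive. List medians near 0 also changed sign in some settings. All 12 counts of genes stayed within 1.5 times under no filter, centring, equal totals and the GC content and length correction, as did the 6 counts without s215 in the filter, computed only for pairs of the other 3 libraries; without s215 in the filter atprmt5 had 334 genes higher and 628 lower than wild type. Counts moved further under 3 settings. A pseudocount of 0.1 gave 639 higher and 962 lower in atprmt5 than wild type, 797 lower in m90 than atprmt5, and 798 higher and 832 lower in m90 than wild type. A mean of at least 5 RPKM, which leaves fewer genes, gave 196 higher in atprmt5 than wild type, 275 lower in m90 and 2810 lower in s215 than atprmt5, and 305 lower in m90 and 3012 lower in s215 than wild type. A threshold of 1.5-fold, which admits more genes, gave 1357 higher and 1884 lower in atprmt5 than wild type, 1578 higher and 1647 lower in m90 than atprmt5, 4199 higher in s215 than atprmt5, 1642 higher and 1794 lower in m90 than wild type, 4197 higher in s215 than wild type and 4793 lower in m90 than s215. The share nearer to wild type moved to 54.0% in m90 and 50.2% in s215 for genes higher in atprmt5 and to 36.4% in s215 for genes lower, at a pseudocount of 0.1, and to 50.5% in s215, 68.8% in m90 and 32.8% in s215 (higher, lower and lower) at a mean of 5 RPKM. The covariances moved to -0.142 and 0.000549 at a pseudocount of 0.1. Of the exon class medians, taken relative to all protein-coding genes, 9 moved and 66 did not, most under no filter (6), where the shift of 1-exon genes in s215 against wild type shrank. Exon classes were not computed with GC content and length removed. Ratios of named genes moved in 504 cases and not in 6306. The cause was not tested where no reason is given. The table holds only nuclear loci, so equal totals and nuclear loci only are 1 setting.

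Among the other list medians under the alternatives, 606 stayed on the same side of the outer 2.5% of random lists, 10 left it and 3 entered it. Histone and ribosomal lists were added to the alternatives last. Those leaving were ferritins in s215 against wild type (percentiles 97.4, 96.8 and 97.1 in 3 settings), cell cycle in m90 against atprmt5 (93.3 at a mean of 5 RPKM) and, with GC content and length removed, core snRNP (97.36 in m90 and 93.2 in s215), SR (97.45 in s215), heat shock (96.9 in m90), core histones (13.7 in s215) and root markers (3.55 in s215), each against wild type. Those entering were arginine methyltransferases in m90 against atprmt5 (99.1), flavonoid genes in s215 against wild type (0.31) and abscisic acid genes in s215 against atprmt5 (98.5). Depth limits single genes under about 1 RPKM, such as FT and PRP8B, and says nothing of variation between plants.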

Other observations

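The gene lists here were chosen after the main results had been seen. Leaf senescence transcripts set s215 apart: 7 of 10 measured genes were at least 2-fold higher than in wild type and 2 lower, at a median of 2.0 above all random lists. NAP, a transcription factor of leaf senescence, was at 511 against 36.8 RPKM, ORE1 at 38.3 against 6.75 and the chlorophyll breakdown gene NYC1 at 113 against 32, while SEN1 and SAG29 were lower. In atprmt5 0 of the 10 were higher and 2 lower than in wild type, and in m90 0 were higher and 3 lower.

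All 12 further root-enriched genes were at least 2-fold lower in s215 than in wild type on the log2(RPKM + 1) scale, at a median of -3.34. The beta-glucosidase gene BGLU21 was at 0.0331 against 33.1 RPKM, and the peroxidase gene PER57 at 0.130 against 18.8. In atprmt5 and m90 the medians of this list against wild type were -0.30 (percentile 1.69) and -0.39 (percentile 0.59), with 2 of 12 lower in atprmt5 and 0 past 2-fold in m90. IRT1 and NRT2.1, by contrast, were higher in atprmt5 than in wild type.

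Rapid touch and wound response genes were intermediate in wild type. In atprmt5 9 of 12 were at least 2-fold lower than in wild type and 0 higher, and in m90 7 were higher and 0 lower, at a median of 1.33. ZAT12 was at 34.2 RPKM in atprmt5, 103 in wild type and 288 in m90, and the xyloglucan enzyme gene TCH4 at 120, 297 and 463. In s215 9 of the 12 were lower than in wild type and 2 higher, TCH3 and WRKY18.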
